A study of Mus musculus with 6 samples.

How the data were processed

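The series holds 6 samples of Lgr5-positive progenitor cells from the cochleae of newborn mice, 4 H3K4me3 libraries and 2 input libraries. The 2 groups are cells treated for 12 h with neomycin and untreated cells. Per the labels' protocols, cochleae of mice carrying a fluorescent reporter in the Lgr5 locus were cultured, and dissociated cells were sorted by that fluorescence. Groups and replicate numbers were taken from the labels. The input libraries were not analysed here.

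The deposited file of each H3K4me3 library is a list of its own peaks, so peaks were called per library. Per the submitters' processing notes, the build was mm10 and the tools named were CASAVA 1.4, Bowtie2, MACS2 and deepTools; their roles, parameters and use of the inputs are not given in the sources used here. Per the file headers, each peak has a start, an end and a summit position, a length in bp and a pileup signal at the summit. The deposited lists also give a fold enrichment (a ratio over the local background) and a -log10 p-value and q-value for each peak, as the authors' peak caller computed them. These are the authors' values for single peaks. They were used to rank or filter peaks within a list, and the median fold enrichment of each list is also given. Positions are 1-based, and length equalled end minus start plus 1 for each peak. The lists contain no read totals, so depth is unknown. The deposited names of the untreated lists give H3K4me2, while the labels give H3K4me3 and 1 antibody for all 4 libraries. The labels were followed, and the mark in the untreated lists is to that extent uncertain.

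Peaks were assigned to genes with an annotation of GRCm38.p6, the assembly of mm10. It lists 21887 protein-coding genes on the main chromosomes with 1 start and 1 end each and no strand. The plan had assumed transcription start sites. In their place, the promoter of a gene was the window of 1 kb either side of the gene end that held peaks in more of the 4 libraries, then of the end with more peak bases, then of the lower coordinate. The treatment labels were not used in that choice, but the longer untreated peaks weigh more where peak bases decide. A promoter was marked in a library when a peak overlapped the window by at least 1 bp. Promoters of shorter transcripts that start inside a gene are not seen by this rule. At promoters marked in all 4 libraries and shared with no other gene, the summits lay a median of 334, 321, 267 and 302.5 bp inside the gene in neomycin replicates 1 and 2 and untreated replicates 1 and 2.

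Promoters were counted that were marked in both libraries of 1 group and neither of the other, and the same was done for regions made by merging overlapping peaks of the 4 libraries. These counts were set beside those of the other 2 ways to part the 4 libraries into pairs. Presence was not tested per gene, because relabelling the libraries in 3 ways allows no p under 0.333. All 696 genes of 21 gene lists, fixed before the data were examined, matched a symbol of the annotation. Lists with at least 5 marked members were tested with a two-sided Fisher exact test against the other promoters marked in at least 1 library, with Benjamini-Hochberg adjustment over 16 lists for each direction. These tests describe the libraries, since genes are not replicates. Endothelium, macrophage and blood, Hox, germ line, and olfactory and liver lists had fewer marked members and were not tested.

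For promoters marked in all 4 libraries, the log2 of the summed length of the peaks touching the window was centred on each library's median and compared with limma 3.58.1 in R 4.3.3, at a Benjamini-Hochberg adjusted p of 0.05. Gene lists were tested on the same values with limma's camera, at its preset correlation of 0.01 and with an estimated correlation. The limma comparison of domain length and the assignment of peaks to promoters were tested on simulated data, while camera was not. With 3282 promoters simulated for the comparison of domain length, 38% of promoters changed by a log2 of 2 and 100% of those changed by 4 were called, and 2.82% of the calls were unchanged promoters. The simulated lengths had no lower limit. Real lengths could not fall below the library's shortest peak, and 309 and 336 promoters lay at the lowest value in neomycin replicates 1 and 2. These percentages therefore do not give the share of real changes that would be called. All planted promoter marks and gene ends were recovered (100% of 2200). The planted genes lay apart from other genes and had peaks at a single end, so this result was nearly fixed in advance. Shared ends, peaks at both ends and missed peaks were not simulated. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

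Genes were named by a rule fixed before the data were examined. It took 20 key genes, up to 4 genes per list and direction in alphabetical order, and the 10 promoters per direction outside the lists with the highest rank, which is the lower of the percentiles of the caller's q in the 2 libraries. For domain length it took, with none past the threshold, the 5 promoters per direction with the smallest p, as values only, and also the 10 broadest domains per group. Predicted genes, taken as symbols of Gm with digits or ending in Rik, were left out of the last 3 parts; 1 locus under another provisional symbol stayed in. Some genes that the rule or the counts include are not reported here by name.

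Alternatives fixed in advance were a window of 2.5 kb, peaks with a -log10 q of at least 10, the strongest 10387 peaks of each list, a peak cover of at least 500 bp of the window or 50% of the merged region, another background for the list tests, no centring, quantile normalization, the replicate number as a block, bases covered within 2.5 kb, and leaving out each library. Chosen after seeing the data were any peak in the gene body or within 1 kb of it, either gene end, promoters shared with no other gene, and for the list tests also leaving out each library, equal list length and the 2.5 kb window. Peaks on unplaced scaffolds and on the mitochondrial genome were left out of all comparisons.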

Results

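H3K4me3, a histone mark found at the promoters of active and poised genes, was profiled by chromatin immunoprecipitation and sequencing in Lgr5-positive progenitor cells of the neonatal mouse cochlea. These supporting cells carry a green fluorescent reporter driven from the Lgr5 locus and were sorted by its fluorescence. The design compared cells exposed for 12 h to neomycin, an aminoglycoside antibiotic that kills sensory hair cells, with untreated cells, and so addressed how the mark is distributed in progenitors after damage. Each group had 2 H3K4me3 libraries, and each had 1 input library that was not analysed here. The labels do not say whether the libraries of a group came from separate cultures, so differences are set only against the spread between these libraries. The peak lists held 14203 peaks in neomycin replicate 1, 11545 in neomycin replicate 2, 15938 in untreated replicate 1 and 10520 in untreated replicate 2. The lists carry no read totals, so the sequencing depth is unknown.

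Most peaks lay at genes in every library. On the main chromosomes, 65.7% of peaks (95% Wilson interval 64.9 to 66.5) were within 1 kb of an end of a protein-coding gene in neomycin replicate 1 and 71.3% (70.4 to 72.1) in neomycin replicate 2. The shares were 72.2% (71.5 to 72.9) in untreated replicate 1 and 75.0% (74.2 to 75.8) in untreated replicate 2. The intervals cover counting error only, and the 2 neomycin libraries lay further apart than the lowest untreated and the highest neomycin library. Windows around the lower coordinate of each gene held a peak in 16.8%, 16.5%, 23.3% and 17.6% of genes in neomycin replicates 1 and 2 and untreated replicates 1 and 2. Around the upper coordinate the shares were 17.0%, 16.3%, 23.2% and 17.7%. Without strand, neither coordinate is known to be the transcription start site. Windows moved 50 to 200 kb away from the lower coordinate held one in 1.65%, 1.75%, 2.57% and 1.69%. Of 21887 protein-coding genes, 11517 had a marked promoter in at least 1 library and 3282 in all 4. A promoter was taken as the 2 kb around the gene end that held peaks in more libraries, chosen without the treatment labels, because the annotation used gives no strand. The chosen end of a gene is therefore not known to be its transcription start site.

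Of 20 key genes fixed before the data were examined, 9 had a peak at the promoter in all 4 libraries. They were Lgr5, the R-spondin receptor that labels these cells, the transcription factors Sox9 and Prox1, the receptor Fgfr3, the Notch pathway genes Notch1, Jag1, Hes5 and Hey1, and the cell cycle inhibitor Cdkn1b. At Lgr5, on chromosome 10 from 115450314 to 115587780 in mm10, the peaks summed to 180 and 329 bp in the neomycin libraries and to 758 and 311 bp in the untreated libraries. Sox2, a transcription factor of the prosensory domain, had a promoter peak in every library except neomycin replicate 1, which had a peak 0.841 kb beyond the gene. Over the whole list of supporting and progenitor cell genes, 31 of 38 were marked in some library and 18 in all 4. Per library, 57.9% and 65.8% of that list were marked with neomycin and 81.6% and 57.9% without.

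Marks on hair cell genes were sparse, and Atoh1 differed between the groups. Atoh1 encodes the transcription factor that initiates hair cell differentiation and lies on chromosome 6 from 64729125 to 64731245. It had 2 peaks at the promoter in untreated replicate 1, summing to 601 bp, and 3 in untreated replicate 2, summing to 955 bp. Neither neomycin library had one, and their nearest peaks lay 1050 kb and 3.17 kb from the gene. Of the other hair cell regulators, Pou4f3 was marked in replicate 1 of both groups and Gfi1 in untreated replicate 1 alone. The promoter of Myo7a, a hair bundle myosin, had no peak in any library, and neomycin replicate 1 had 1 peak inside the gene. Of 42 hair cell genes, 19 were marked somewhere and 1 in all 4 libraries, and 14.3% and 14.3% were marked with neomycin against 38.1% and 19.0% without. Atoh1 was the only member of this list that was marked in both untreated libraries and neither neomycin library, and none had the opposite pattern.

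Trp53 and Cdkn1a, genes of the p53 response, had peaks in or at the gene in both neomycin libraries and in neither untreated library, while the list of p53 and apoptosis genes did not pass the Fisher exact test in either direction (adjusted p 1.0 for neomycin only and 0.909 for untreated only). Trp53, which encodes p53, lies on chromosome 11 from 69580348 to 69591873 and was marked in both neomycin libraries, with 187 and 243 bp of peaks, and in neither untreated library. This promoter is shared with Wrap53, and untreated replicate 1 had a peak that ended 1.24 kb outside the Trp53 gene, so that Trp53 was not neomycin only with a window of 2.5 kb. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, lies on chromosome 17 from 29090979 to 29100722. It had no peak within 1 kb of either end, but 5 peaks inside the gene in neomycin replicate 1 and 3 in neomycin replicate 2, the first of them 2.85 and 2.87 kb from the annotated gene start. The nearest untreated peaks lay 57.9 and 83.1 kb away. Bbc3, a p53 target that promotes apoptosis, had 3, 3, 2 and 2 peaks inside the gene in neomycin replicates 1 and 2 and untreated replicates 1 and 2, and none at its ends.

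**Figure D1:**
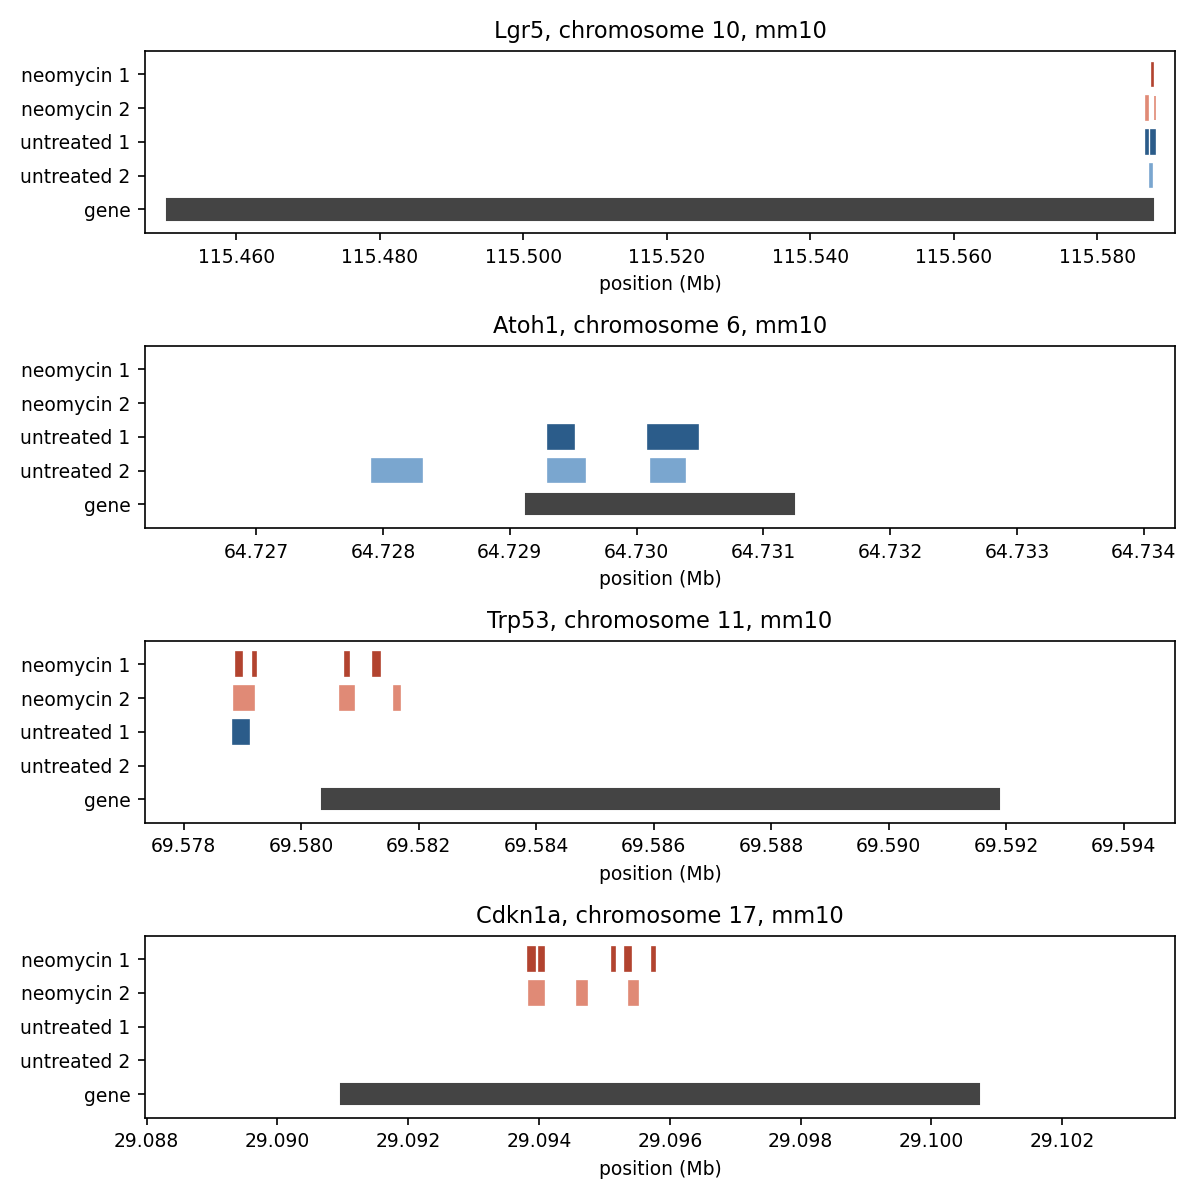
H3K4me3 peaks of the 4 libraries around Lgr5, Atoh1, Trp53 and Cdkn1a. The horizontal axis is the mm10 position in Mb, each coloured block is a peak of the named library, and the dark bar is the annotated gene. Atoh1 has peaks in the 2 untreated libraries only, Cdkn1a has 5 and 3 peaks in the neomycin libraries only, and Lgr5 has peaks in all 4.

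More promoters were marked in the untreated cells alone than in the neomycin cells alone. In total, 1024 promoters had a peak in both untreated libraries and in neither neomycin library, and 306 had the reverse, a ratio of 3.35 (95% interval 2.95 to 3.8 from counting error). Presence of a peak was not tested per gene, since 4 libraries part into pairs in only 3 ways and relabelling them gives no p below 0.333. The other 2 ways were uneven too, with larger ratios. Pairing by replicate number left 569 promoters to the replicates 1 and 125 to the replicates 2, a ratio of 4.55, and the crossed pairs left 116 and 542, a ratio of 4.67. The larger count of each lay below 1024 and above 306, and untreated replicate 1, which has the longest list, was on the larger side in all 3 ways. With lists of equal length the ratio was 2.88 for the treatment and 1.29 and 1.55 for the other pairings, and in both of these the pair with neomycin replicate 2 then had the larger count. The neomycin-only count depended on the threshold of the caller, and both counts on the bases of the window covered. With peaks of -log10 q of at least 10 alone, 1351 promoters were marked in the untreated cells alone and 1 in the neomycin cells alone, and when at least 500 bp of the window had to be covered, the counts were 1647 and 0. They depended on each library too, with 469 to 1232 neomycin-only promoters and 1258 to 2384 untreated-only promoters when 1 library was left out; without untreated replicate 1 they were nearly equal, at 1232 and 1258.

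**Figure D2:**
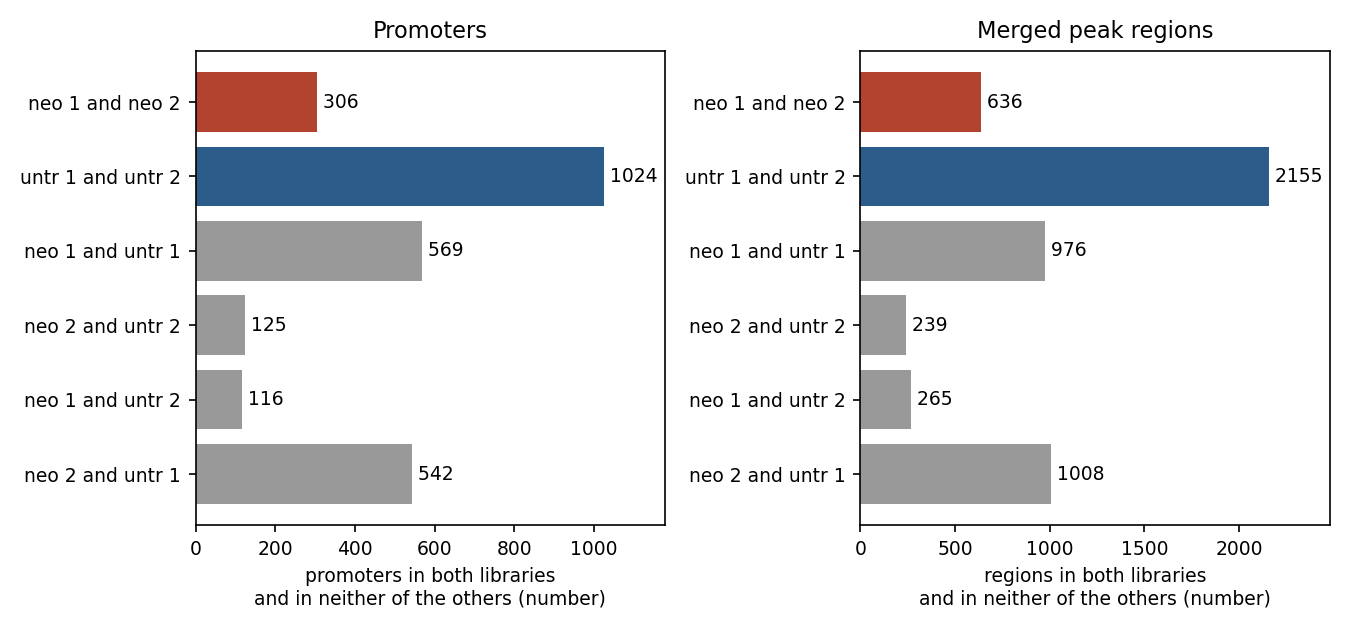
Promoters (left) and merged peak regions (right) found in both libraries of a pair and in neither of the other pair. Each bar is 1 pair of libraries and its length is a count; neo stands for neomycin and untr for untreated. The red and blue bars are the treatment groups, with 306 and 1024 promoters, and the grey bars are the pairs that mix them.

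Some developmental signalling genes were marked in the untreated cells alone, but no such list passed the test. Of 44 marked genes of the FGF, BMP and Hedgehog pathways, 7 (15.9%) were untreated only, against 8.86% of other marked promoters. They included the ligands Bmp2 and Fgf2 and the receptors Bmpr1a and Fgfr2. The shares of the Notch list (6.67%) and of supporting and progenitor cells (3.23%) lay below those of other marked promoters (8.9% and 8.91%). Of 45 marked Wnt pathway genes, 6 (13.3%, against 8.87% of others) were untreated only and 0 neomycin only. The 6 included Ctnnb1, which encodes beta-catenin, the nuclear effector Tcf7, the target Sp5 and the secreted Wnt inhibitor Notum. At Ctnnb1 the peaks summed to 741 and 380 bp in the untreated libraries, and at Tcf7 to 290 and 861 bp. Ctnnb1 also had a peak inside the gene in neomycin replicate 2, as Bmp2 and Bmpr1a had in neomycin replicate 1, and none of the 3 was untreated only with a window of 2.5 kb. Of 30 marked Notch pathway genes, Dll4 and Notch4 were untreated only, although Notch4 had a peak inside the gene in neomycin replicate 2. The annotation does not identify the chosen end of any of these genes as its start. This includes Sp5 and Notch4, where the window lay at the upper coordinate. Eya1, a transcriptional co-activator needed for inner ear development, was the 1 untreated-only gene among the 31 marked supporting and progenitor cell genes, with 358 and 370 bp. It had a peak inside the gene in neomycin replicate 1 as well, and was not untreated only with the 2.5 kb window or when peaks in the gene body counted. The Wnt target Axin2 had no peak at its ends in any library. It had 5, 2, 2 and 2 peaks inside the gene in neomycin replicates 1 and 2 and untreated replicates 1 and 2. The Wnt-responsive cell cycle gene Ccnd1 had a promoter peak in replicate 1 of each group. In Fisher exact tests (two-sided, Benjamini-Hochberg over 16 lists), none of these lists differed from the other marked promoters (adjusted p 0.565 for FGF, BMP and Hedgehog, 0.769 for Wnt, 1.0 for Notch and 0.904 for supporting and progenitor cells).

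Stress genes had the opposite balance, which did not pass the test. Of 40 marked stress and immediate early genes, 3 were neomycin only and 0 untreated only, against 2.64% and 8.92% of other marked promoters. The 3 were Ddit3, a transcription factor of the unfolded protein response, Ier3, an immediate early gene, and Prdx1, a peroxide-reducing enzyme. Prdx1, on chromosome 4 from 116685599 to 116700000, had 170 and 115 bp of peaks in the neomycin libraries, and the nearest untreated peaks lay 21.1 and 21.0 kb away. Ddit3 shares its gene end with Mbd6 and had untreated peaks 1.94 and 2.01 kb away. Ier3 shares its end with Flot1, and its nearest peak in neomycin replicate 1 lay 0.615 kb outside the gene. The annotation does not identify that end as the start of Ier3. The Fisher exact p was 0.0894 (adjusted p 1.0) for the neomycin-only genes and 0.0465 (adjusted p 0.372) for the absence of untreated-only genes. Of 33 marked p53 and apoptosis genes, Trp53 was neomycin only, while Bcl2, which restrains apoptosis, and Pmaip1, which promotes it, were untreated only (adjusted p 1.0 and 0.909). Bcl2 had 2 peaks inside the gene or within 1 kb of it in neomycin replicate 1. Of 14 marked inflammation genes, Irf1 and Socs3 were untreated only, although Socs3 had a peak inside the gene in each neomycin library (adjusted p 0.817).

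Among markers of cells other than supporting cells, the mesenchyme and fibrocyte list had the smallest p. Of 10 marked genes of that list, 4 were untreated only, namely Coch, a protein of cochlear fibrocytes, and the transcription factors Twist1, Prrx2 and Sp7, against 8.86% of other marked promoters (Fisher exact p 0.00843, adjusted p 0.135). Untreated peaks touched the genes Coch, Twist1 and Prrx2. The nearest ones to Sp7 lay 0.441 and 0.788 kb outside the gene, at an end that the annotation does not identify as its start. The list passed the threshold when untreated replicate 1 was left out (5 of 10, adjusted p 0.0388) or untreated replicate 2 (7 of 10, adjusted p 0.00446). Without neomycin replicate 1 or 2 the odds ratio was 2.56 and 2.81, against 6.85 with all libraries (adjusted p 0.572 and 0.91). With lists of equal length the share was 12.5%, or 1 of 8 genes, against 10.1% of others (p 0.574, adjusted p 1.0). Per library, 8.0% and 4.0% of the list were marked with neomycin and 32.0% and 20.0% without. For spiral ganglion neurons the shares were 15.4% and 26.9% against 42.3% and 23.1%, and no gene of that list was marked in both libraries of 1 group alone. Glia gave Pou3f1 as untreated only among 7 marked genes, melanocytes and stria gave Tbx2 among 10, with 2 peaks inside the gene or within 1 kb of it in neomycin replicate 1, and endothelium gave Flt1 as neomycin only among 3. Macrophage and blood markers were marked in 0.0% and 4.0% of 25 genes with neomycin and 4.0% and 4.0% without. Hox genes, germ line genes, and the olfactory and liver genes that these cells should lack were marked in at most 18.2% of each list. Tex14, a germ line gene that shares its end with Rad51c, was neomycin only.

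Housekeeping lists showed how complete the marking was. Of 49 cytosolic ribosomal protein genes, 65.3% and 51.0% were marked in the neomycin libraries and 81.6% and 59.2% in the untreated libraries, and 10 genes were marked in all 4. Rpl7, Rps15 and Rpl38 were untreated only, and Rpl24 and Rpl35 neomycin only. With the 2.5 kb window none of these except Rpl35 had such a pattern, and Rpl38 had 1 and 2 peaks inside the gene or within 1 kb of it in the neomycin libraries. Of 40 mitochondrial and oxidative phosphorylation genes, 57.5% and 65.0% were marked with neomycin and 77.5% and 67.5% without, with Sdha and Ndufa4 untreated only and Ndufa9 neomycin only. Of 42 marked cell cycle genes, Top2a was neomycin only and Rbl1 untreated only. The H3K4 methylation enzymes and readers had no member of either kind among 26. In the Fisher exact tests, adjusted p was 0.565 to 1.0 in both directions for these 4 lists and for hair cells, spiral ganglion neurons, glia, and melanocytes and stria. Genes that every cell uses thus lacked a peak in some libraries, and a missing peak is read here as not called rather than as absence of the mark.

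**Figure D3:**
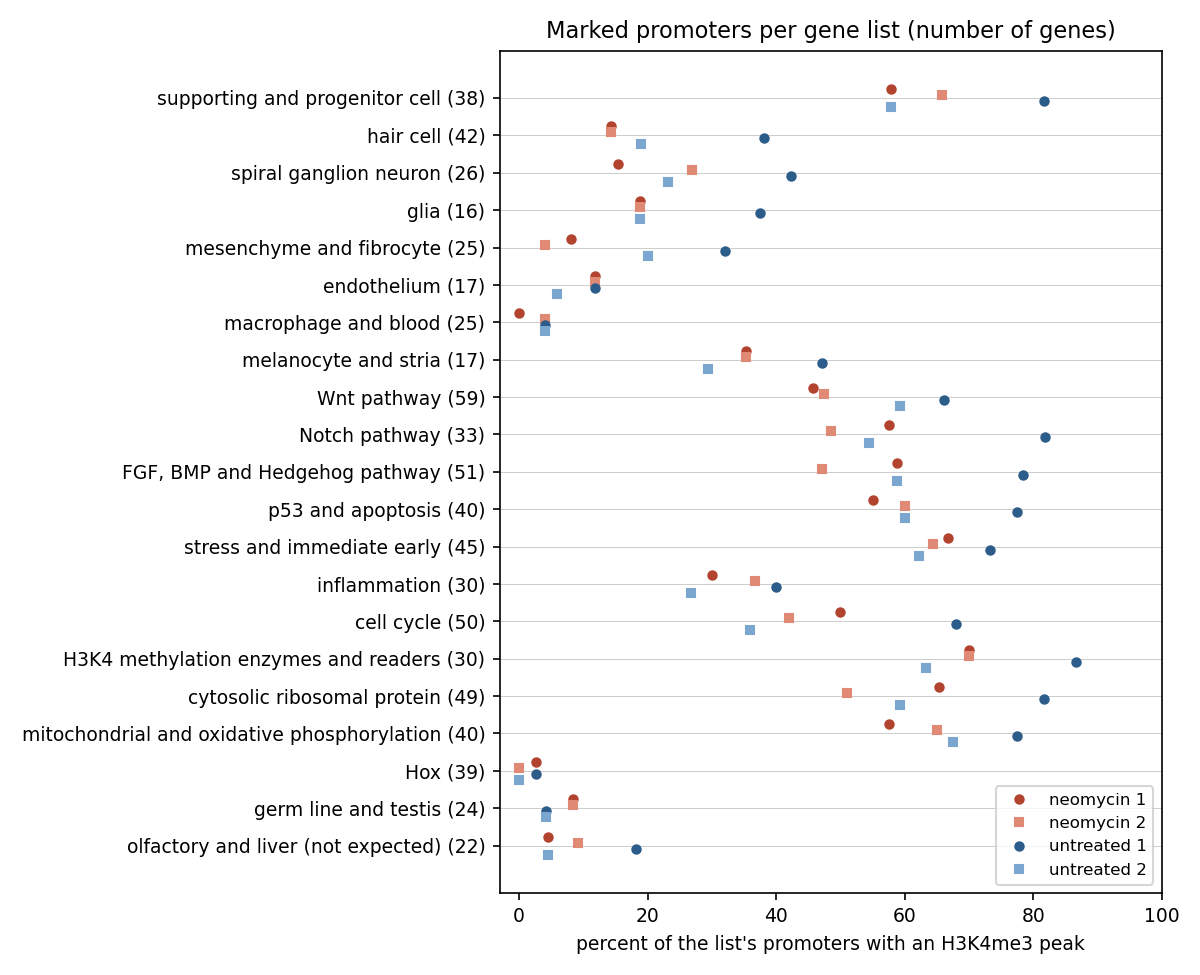
Percent of the promoters of each of 21 gene lists that had a peak in each library. The horizontal axis is the percent of the list's genes, the number of genes is in brackets, and each point is 1 library. Untreated replicate 1 has the highest share in most lists, and the mesenchyme and fibrocyte list has 8.0% and 4.0% with neomycin against 32.0% and 20.0% without.

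Outside the lists, the strongest promoters of each direction were taken by the rank of their peak within its own list. With neomycin alone, Gstp1, a glutathione transferase of the detoxification response on chromosome 19 from 4035411 to 4037912, had 388 and 293 bp of peaks at percentiles 86.5 and 92.4 of the caller's q, and the nearest untreated peaks were 22.7 and 22.8 kb away. Also in this set were Ache, which encodes acetylcholinesterase and shares its gene end with Ufsp1, the DNA replication factor Ciz1, the endosomal protein Tom1, the mitochondrial protein Cmc1, Sec14l2, Mpp2, and the pair Bloc1s3 and Trappc6a, which share an end. In the untreated cells alone, Ppp4r1, a regulatory subunit of a protein phosphatase, had 861 and 1162 bp at percentiles 99.7 and 94.1, and the transcriptional corepressor Lcor had 1053 and 1454 bp at percentiles 98.9 and 94.1. The others were Dgat1, which completes triglyceride synthesis, the peroxisomal gene Pex6, Iws1, Spg7, the protease Capn2, Trim7, the cardiolipin synthase Crls1 and Nelfcd, part of the complex that pauses RNA polymerase. With peaks in the gene body counted, Trim7, Crls1 and Mpp2 no longer belonged to 1 group alone.

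Untreated-only promoters were not only the weakest marks. Of 6851 promoters marked in both untreated libraries, 14.9% had no neomycin peak. Over 4 equal bins of the weaker of the 2 untreated percentiles, from lowest to highest, the share was 21.0%, 15.1%, 12.5% and 10.3%. Of 4677 promoters marked in both neomycin libraries, 6.54% had no untreated peak, with 7.87%, 6.95%, 5.23% and 6.45% over the same bins.

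Without reference to genes, the peaks merged into 24272 regions, and the same direction appeared. In all, 2155 regions were found in both untreated libraries alone and 636 in both neomycin libraries alone. Of these, 73.1% and 66.7% lay at a gene end, against 80.9% of the 2797 regions found in all 4 libraries. The other pairings gave 976 and 239 regions by replicate number and 265 and 1008 for the crossed pairs. The untreated libraries shared the most, with a Jaccard index of 0.498 for regions and 0.656 for promoters. The neomycin libraries shared less with each other (0.261 and 0.5) than with untreated replicate 1 (0.32 and 0.333 for regions, 0.569 and 0.551 for promoters). When peaks had to cover 50% of a region, the counts were 6036 and 246, and at -log10 q of at least 10 they were 1435 and 4. Leaving out 1 library gave 3129 to 5898 untreated-only and 821 to 4868 neomycin-only regions, and without neomycin replicate 2 the direction turned, with 3683 and 4868.

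The promoters marked in all 4 libraries were compared by the summed length of their peaks. After centring each library on its median, limma called 0 of 3282 promoters wider and 0 narrower with neomycin at an adjusted p of 0.05, while 122 and 194 had an unadjusted p under 0.05. Adjusted over the list alone, 0 of 124 genes of the fixed lists were called. The smallest p were those of Pcbp1, Ncoa2, Zbtb1 with Zbtb25, and Tshz3 in the narrower direction and of Itgb1bp1 with Cpsf3, Etfdh, Klf12 and Ccdc189 in the wider direction. Pcbp1, an RNA-binding protein, had 53 and 110 bp with neomycin and 1650 and 1421 bp without, a log2 ratio of -2.75 ± 0.62 (SE, 2 libraries per group) after centring, and an adjusted p of 0.0606 by limma. The shortest peaks of the neomycin libraries were 48 and 110 bp. Itgb1bp1 with Cpsf3 had 188 and 234 bp without neomycin, where the shortest peaks were 187 and 234 bp. The ratios and SE of these genes thus rest on values at or near the lower limit in 1 group. Without neomycin replicate 1 the calls were 22 wider and 54 narrower, and without neomycin replicate 2 they were 91 and 161. Before centring, the median promoter had a summed peak length of 123 and 230 bp with neomycin and 552.5 and 454 bp without, and limma then called 928 narrower and 0 wider.

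None of the lists fixed in advance passed the test of domain length. In limma's camera test with a preset correlation, 0 of 9 lists passed. Oxidative phosphorylation genes came nearest in the wider direction, with 9 of 11 above zero and a median log2 ratio of 0.55 (p 0.0552, adjusted p 0.248), and H3K4 methylation enzymes and readers in the narrower direction, with 5 of 14 above zero and a median of -0.16 (p 0.0502, adjusted p 0.248). With an estimated correlation, the smallest adjusted p was 0.721. Among key genes, Lgr5 had a log2 ratio of 0.58 ± 0.63 (SE) and Sox9 of -0.71 ± 0.63, with adjusted p of 0.839 and 0.772 by limma.

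The 10 broadest promoter domains of each group, by the smaller summed peak length of its 2 libraries, belonged to different genes. A domain here can be several separate peaks. In the untreated libraries they were those of the nuclear receptor coactivator Ncoa2, the kinase Dyrk1a, the transcription factor Sall3, Zbtb1 with Zbtb25, the chromatin readers Ing1 and Ing2, the chromatin remodelling subunit Arid2, the histone H3K4 methyltransferase Kmt2c, and H2-DMa. Ncoa2 had the longest, with 2070 and 2015 bp against 48 and 258 bp with neomycin. Sall3 had 1785 and 1764 bp and no promoter peak in either neomycin library, which had 3 and 1 peaks inside the gene or within 1 kb of it. In the neomycin libraries the broadest were Dock4 with Zfp277, Mmp15, Limch1, Capza1 with St7l, Hjurp, Trip11, Klf12 and a locus without a named gene on chromosome 12. At Dock4, 6 and 3 peaks summed to 568 and 719 bp with neomycin, against 2 and 2 peaks with 802 and 1129 bp without.

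The length of the shortest peak also differed between the libraries. It was 48 bp in neomycin replicate 1, 110 bp in neomycin replicate 2, 187 bp in untreated replicate 1 and 234 bp in untreated replicate 2, and 22.1%, 17.8%, 9.13% and 11.7% of the peaks had exactly that length. The 2 groups did not overlap in this value, so that the uncentred lengths compare the treatments together with this property of the lists. The deposited untreated lists are also named for H3K4me2, while the labels give the same H3K4me3 antibody for all 4 libraries; the labels were followed here.

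**Figure D4:**
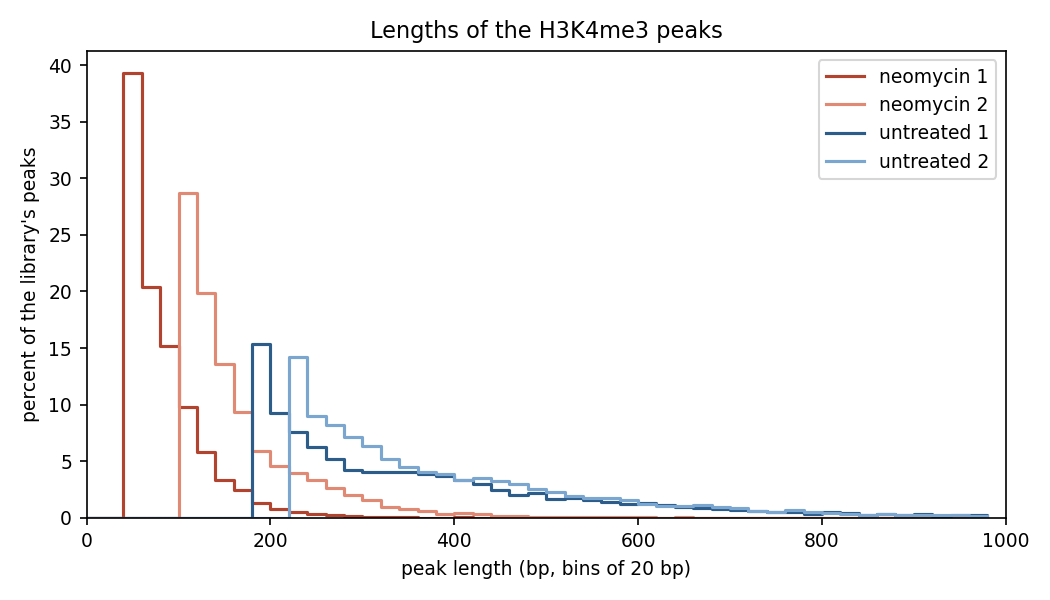
Lengths of the H3K4me3 peaks in the 4 libraries. The horizontal axis is the peak length in bins of 20 bp up to 1000 bp, the vertical axis is the percent of the library's peaks, and each line is 1 library. Each library starts at its own shortest length, 48 and 110 bp with neomycin and 187 and 234 bp without.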

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

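The unplaced scaffold JH584304, which the comparisons do not use, held a larger share of the peaks in both neomycin libraries than in either untreated library. The share was 1.42% (202 peaks, 95% Wilson interval 1.24 to 1.63) in neomycin replicate 1 and 1.11% (128 peaks, 0.933 to 1.32) in neomycin replicate 2, against 0.364% (58 peaks, 0.282 to 0.47) in untreated replicate 1 and 0.428% (45 peaks, 0.32 to 0.572) in untreated replicate 2. The bases covered went the other way, with 23310 and 46038 bp in the neomycin libraries and 75520 and 75207 bp in the untreated libraries, so the neomycin peaks there were more numerous and shorter. No explanation was tested.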

How the results depend on the processing

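The alternatives on gene body, either gene end and unshared promoters, and for the list tests also equal list length, the 2.5 kb window and leaving out libraries, were chosen after seeing the data. Of 69 alternative values, 42 stayed within 1.5 times the reported count and 27 did not. Most of the 42 were counts of 0, for gene lists and domain length, that stayed at 0. For the promoter and region counts, more alternatives moved than stayed. The 306 neomycin-only promoters became 1 with peaks of -log10 q of at least 10, 0 with at least 500 bp of the window covered, and 469 to 1232 without 1 library. The 1024 untreated-only promoters became 1647 with at least 500 bp covered and 1258 to 2384 without 1 library. The 636 neomycin-only regions became 246 with 50% of the merged region covered, 4 at the stricter q, and 821 to 4868 without 1 library. The 2155 untreated-only regions became 6036, 1435 and 3129 to 5898 in the same order. Leaving out a library raises these counts by construction, since the group left with 1 library is judged on that library alone; the lists' q ranges differ (732, 269, 6167 and 2179 peaks reached -log10 q of 10 in neomycin replicates 1 and 2 and untreated replicates 1 and 2), which accounts for the loss of neomycin-only calls at the stricter q. For cover, the neomycin peaks are too short to reach 500 bp often. With lists of equal length the promoter counts were 381 and 1098, with any peak in the gene body 341 and 986, and with unshared promoters 204 and 884. In each of these settings the untreated-only count was the larger, but without untreated replicate 1 it was 1258 against 1232 promoters, and without neomycin replicate 2 it was 3683 against 4868 regions.

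Among gene lists, 0 were called as reported and 0 to 1 without 1 library, the 1 being mesenchyme and fibrocyte without either untreated library; the cause was not tested. For domain length, limma's calls were 0 wider and 0 narrower as reported, 0 and 928 without centring, 0 to 91 wider and 0 to 161 narrower without 1 library, where the lone library is assumed to vary like the other group. Camera called 0 lists in each alternative. The uncentred calls follow from the median log2 shift of -1.57. At -log10 q of at least 10, 0 promoters were marked in all 4 libraries, so that setting gave no value for domain length. With the replicate number as a block, limma called 0 and 0 promoters (100 and 174 at an unadjusted p under 0.05) and camera 0 lists. The labels do not say what a shared replicate number stands for; the deviations of same-numbered libraries correlated at -0.0235, which gives no sign of pairing and does not exclude a shared culture or day. Unknown depth limits what an absent peak shows.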

Other observations

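Lists of equal length were an alternative fixed in advance; the bound set on their ratio, their use for the pairs that mix the treatments and the other tests in this part were chosen after the results they bear on had been seen. Apart from Cdkn1a, Tbx2 and Sall3, the genes in this paragraph and the next were named after their values were seen. Cdkn1a was 1 of 2 genes with at least 3 peaks inside the gene or within 1 kb of it in both neomycin libraries and none in either untreated library. The other was Nr1d1, a nuclear receptor of the circadian clock. Mid1 and Samd1 had the reverse pattern. Pairs that mixed the treatments gave 3 genes for the replicates 1 (Mapk8ip3, Mgat5 and Plppr1), 2 for neomycin replicate 2 with untreated replicate 1 (Arhgef17 and Trerf1) and 0 for the other 2 pairs, so the count alone does not set the treatment apart.

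Genes of developmental transcription factor families, taken by symbol prefix, were compared with other promoters. Of 103 such genes marked in both untreated libraries, 22 (21.4%) had no neomycin peak at the promoter, against 1002 of 6748 others (14.8%). They included Emx2 and Lhx2, the proneural gene Neurog2, and Barhl2, Gbx1, Olig1, Tbx2, Sall3 and Sall4. Of 65 marked in both neomycin libraries, 1, Sall2, had no untreated peak. A loss more frequent in these families is a hypothesis that the test left open (two-sided Fisher exact p 0.0704), and within 4 bins of peak strength the odds ratio was 1.57 with a 95% interval of 0.965 to 2.54.

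Promoters at gene ends shared by several genes were less often untreated only. Counting each shared end once, 7.34% of 954 untreated-only ends were shared (95% Wilson interval 5.85 to 9.17), against 19.4% of 253 neomycin-only ends (15.0 to 24.7) and 17.1% of 2782 ends marked in all 4 libraries (15.8 to 18.6; Fisher exact p 1.61e-07 between the first and the second). Within those bins, the Mantel-Haenszel odds of a missing neomycin peak were lower at shared ends, with an odds ratio of 0.452 (0.35 to 0.583). For a missing untreated peak the ratio was 1.16 (0.839 to 1.6). These odds come from the promoters in which the pattern was seen, so they describe it and do not test a cause. Whether a shared window holds the marks of both promoters was not tested.

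More promoters were marked in the untreated cells alone than in the neomycin cells alone. Unequal numbers of peaks alone are argued against, since with lists of equal length the ratio was 2.88 (2.56 to 3.24). The ratios of the pairs that mix the treatments went from 4.55 and 4.67 to 1.29 and 1.55. Even so, each neomycin library then marked fewer promoters than each untreated library. The 3612 promoters shared by the neomycin libraries were 63.5% and 55.4% of those marked in replicates 1 and 2. For the untreated libraries, the 5767 shared promoters were 75.5% and 77.0%. Equal lists therefore cannot decide whether unequal numbers of marked promoters gave the ratio. Independent misses of weak peaks in each neomycin library remain open. Within the same bins, 1024 promoters were missed by both where 780.9 were expected, a ratio of 1.31 (1.23 to 1.39), which lies inside the 1.16 to 1.51 of the pairs that mix the treatments; the neomycin-only promoters reached 2.46 (2.18 to 2.73). A difference in the caller's fragment length, which is not given and is only inferred here from the shortest peak, cannot be told apart from the treatment, since that peak was at most 110 bp in the neomycin libraries and at least 187 bp in the untreated ones. The median fold enrichment of the peaks also separated the groups, at 5.9 and 6.0 with neomycin and 7.44 and 7.22 without. A difference in enrichment between the libraries was not tested and cannot be told apart from the treatment either. An effect of neomycin on the mark stays open beside these.

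Promoter domains were longer in the untreated libraries. If the shortest peak reflects the fragment length of the caller, which was not measured, that length could account for this, because the median domain divided by the library's shortest peak was 2.56 and 2.09 with neomycin and 2.95 and 1.94 without, which no longer separates the groups, and the ratio of the group means was 1.05. An effect of neomycin on domain length was not tested apart from it.

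The untreated lists were deposited under a name for H3K4me2. If the untreated libraries hold another mark than the neomycin libraries, a lower share of peaks at gene ends than in both neomycin lists would follow; the lowest untreated share was instead 0.9 percentage points above the highest neomycin share, a gap smaller than that between the 2 neomycin libraries. The name and the labels therefore cannot be told apart by this value. H3K4me2 lists may also be longer, as the untreated domains were, so the comparison of treatments may hold a difference of mark.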
